A study of Oryza sativa with 6 samples.

How the data were processed

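Root RNA of 14-day-old WT, RCc3::OsERF71 and GOS2::OsERF71 rice plants was measured with 2 arrays per group. Per the labels' protocols, messenger RNA was purified on an Oligotex column system, and double-stranded cDNA was labelled with Cy3-carrying 9-mer primers, so the array had 1 colour. The labels name the molecule as total RNA. The probe files hold the scanner intensity of each probe, neither background corrected nor normalized, extracted with NimbleScan 2.5.26 per the file headers. A second kind of file, 1 per array, holds the authors' intensity per feature on a linear scale, made with RMA per the submitters' processing notes. The deposited series table holds the same RMA values rounded to whole numbers, a normalized score and not a count, for 22226 of the features. The rule by which the authors left out the other features is not given in the sources used here, nor are the settings of RMA.

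The analysis began from the scanner intensities. Probes were corrected with normexp (offset 50), converted to log2, and the 274664 gene probes were quantile normalized between arrays. Median polish then gave 1 value for each of 27614 features. Of these, 27431 had 10 probes and 144 had a single probe, mostly organelle genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 6 arrays, with 3 residual degrees of freedom and 5.41 prior degrees of freedom, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all features of a contrast. A feature was called at an adjusted p under 0.05. A random effect or block was not part of the fit. The p-values rest on 2 arrays per group, and the median standard error of a contrast was 0.0835 on the log2 scale. The unadjusted p was under 0.05 for 21761, 21944 and 7571 features in RCc3::OsERF71 against WT, GOS2::OsERF71 against WT and RCc3::OsERF71 against GOS2::OsERF71.

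The 114547 random probes of the array, which match no gene, gave the background. They were carried through each array's own normalization and combined into 11454 sets of 10 probes, which were tested like gene features. A feature was above background on an array if it exceeded the 95th percentile there of random sets with as many probes. Where no array of a group exceeded it, the brighter group's mean was set against the floor, per array the higher of the floor and the measured value, and the fold change is given as "at least". The floor was at first the 95th percentile of single random probes for all features. It was changed to sets of matching size after the values of the named features had been seen, because averaging over probes lowers the spread of background. With the first floor the Knamycin feature value was 48.9 times the WT floor in RCc3::OsERF71 and 46.7 times in GOS2::OsERF71, in place of 105.5 and 100.9 times the WT mean, and AK065283 was higher by at least 12.5-fold in RCc3::OsERF71, in place of 38.1-fold. The bounds of the other IDs in RCc3::OsERF71 were 6.32-fold in place of 19.3-fold for AK100853, 4.62-fold in place of 17.5-fold for AK101283 and 3.68-fold in place of 13.9-fold for AK064432. Between the lines they were 2.49-fold in place of 9.43-fold for AK101283 and 1.42-fold in place of 5.36-fold for AK064432. Probes at the scanner ceiling of 65535 were kept, between 37 and 232 gene probes per array.

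Gene names came from an exact match of probe positions to gene starts in the RefSeq gene table of the plastid and mitochondrial genomes. This matched 104 of 108 plastid features and all 53 mitochondrial features to 1 gene each. At 2000 shifted positions at most 2 plastid and 1 mitochondrial features matched. For the nuclear features 0 array IDs were found in the table. The pathway lists and the 3 locus numbers fixed before the data were examined could therefore not be tested, nor could the change of OsERF71. In place of those lists 12 groups of organelle genes were formed by gene symbol, after probe brightness on 1 WT array had been seen and before any contrast was computed, and 10 sets of 5 or more features, including all plastid and all mitochondrial features, were tested in each of 3 contrasts with camera, with a preset correlation of 0.01 and with an estimated one, adjusted over all sets and contrasts. The fixed rule for named genes took, for each contrast to WT, the 8 largest rises and 8 largest falls among called features whose arrays did not overlap and the 2 largest changes of up to 8 lists, and 5 of each for the contrast between lines. It was applied to the features that had a name. Of the features without one, the 2 largest rises and 2 largest falls in RCc3::OsERF71 are given by ID. The chromosome of a cDNA feature was read from the block of probe numbers it shares with locus features. Within a block positions rose with probe number, and the 2 kinds of feature ended within 0.674% of the same position.

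The overlap of the 2 contrasts to WT was compared with 100 simulations of unchanged groups, in which all arrays varied independently by the spread between replicates. The whole chain from probes to calls was tested on simulated probe values with 200 of 27614 features changed in RCc3::OsERF71 against WT. It recovered 100% of the features changed by 1 or -1 on the log2 scale, 32% of those changed by 0.5 and 48% of those changed by -0.5, and 5.41% of its calls were unchanged features. The simulation held few changed features, no date effect and no shift of background. In the data 77.4% and 78.2% of features were called against WT, so these shares do not give the error rate of those contrasts.

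Alternatives fixed before the data were examined covered background correction, normalization, the summary over probes, the authors' own values, a filter on dim features, the variance model, a fit to 2 groups, the replicate number as a block, the date of each array as a random block, and leaving out each array in turn. The arrays fell on 4 dates, given in file names: both WT arrays on 1, both GOS2::OsERF71 arrays on another, and the RCc3::OsERF71 arrays on 2 more.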

Results

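Transcript levels were measured in roots of 14-day-old rice plants (Oryza sativa, cultivar Nipponbare) grown under normal conditions. Wild-type (WT) plants were compared with plants that overexpressed OsERF71, an AP2/ERF-type transcription factor, from either of 2 promoters. The RCc3 promoter is active mainly in roots, and the GOS2 promoter is active throughout the plant. Each of the 3 groups had 2 arrays, 6 in all, and the labels describe the replicates as separate cultures. The 1-colour array carried 27614 features, of which 20507 were named by a cDNA accession, 6941 by a rice locus number, 108 by a plastid protein, 53 by a mitochondrial protein and 5 by a marker gene used in plant transformation. Median gene-probe intensity ranged from 2385 in RCc3::OsERF71 replicate 1 to 4923 in WT replicate 1. The share of gene probes brighter than the 95th percentile of the array's random probes, which match no rice gene, was 78.2% and 77.3% in WT, 70.9% and 72.0% in RCc3::OsERF71, and 72.2% and 72.3% in GOS2::OsERF71. Replicates of a group correlated across features at r = 0.9973 in WT, 0.9961 in RCc3::OsERF71 and 0.9984 in GOS2::OsERF71. The number of arrays limits the precision of every comparison.

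The level of OsERF71 itself was not analysed here. The files do not pair cDNA accessions or locus numbers with gene names, and of 3 locus numbers fixed beforehand for OsERF71, RCc3 and GOS2, 0 were among the array's feature IDs. The named results below therefore concern the marker genes and the genes of the plastid and mitochondrial genomes.

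Features for 2 marker genes were bright in both overexpression lines. The kanamycin-resistance feature, which the array names Knamycin, had a mean normalized log2 intensity of 15.35 in RCc3::OsERF71 and 15.28 in GOS2::OsERF71 against 8.63 in WT. The log2 difference of this feature value from WT was 6.72 ± 0.15 (standard error) in RCc3::OsERF71 (limma, adjusted p = 2.3e-08) and 6.66 ± 0.15 in GOS2::OsERF71 (limma, adjusted p = 4.9e-08). The WT value was mostly background, since 3 of the 4 Knamycin probes were not above it on either WT array. From the lowest line array to the background floor these 3 probes were brighter by at least 44.6-fold, 47.5-fold and 46.9-fold, and the fourth was 21.8-fold brighter than the higher WT array. The feature for sGFP, a green fluorescent protein, was 24.1-fold higher in RCc3::OsERF71 (4.59 ± 0.12; limma, adjusted p = 5.9e-08) and 22.9-fold higher in GOS2::OsERF71 (4.52 ± 0.12; limma, adjusted p = 1.2e-07). All 4 line arrays lay above both WT arrays for each of these 2 features. The line values of sGFP were 15.63 to 15.79, and 1 of its 4 probes was saturated on 1 line array. In WT sGFP was also above background, at 11.37 and 10.98 against floors of 8.51 and 8.61. All 4 of its probes were above background on both WT arrays, and the source of this WT signal was not tested. Hygromycin, a resistance marker, was called in RCc3::OsERF71 (log2 difference 0.76; limma, adjusted p = 3.5e-05) and in GOS2::OsERF71 (0.87; limma, adjusted p = 1.9e-05). Its WT values of 8.65 on each array lay just above a background floor of 8.48 and 8.55, and the floor was 8.75 to 8.95 on the line arrays. Random sets of 5 probes, the number of this feature, reached 0.697 and 0.703 at the 95th percentile of their change. They reached 0.90 and 0.91 at the 99th. The changes of Hygromycin lay between these percentiles, so no rise above the background shift is claimed. Bar, the herbicide-resistance marker, was called in RCc3::OsERF71 (log2 difference 0.59; limma, adjusted p = 0.0036) and in GOS2::OsERF71 (0.92; limma, adjusted p = 0.00028). Both WT arrays and RCc3::OsERF71 replicate 1 were not above background for Bar, whose floor was 8.85 and 8.96 in WT and 9.14 to 9.35 in the lines, so no fold change is given. With the authors' values the call for Bar in RCc3::OsERF71 was lost (log2 change 0.46, adjusted p = 0.059). The gus reporter was not above background on any of the 6 arrays.

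**Figure D1:**
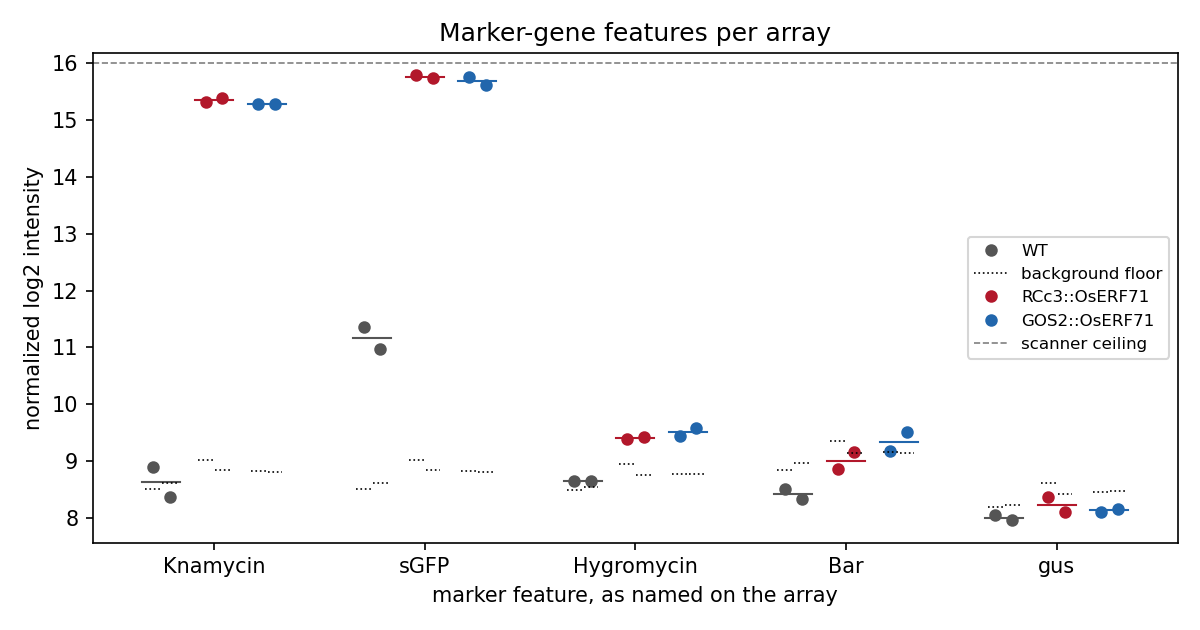
Normalized log2 intensity of the 5 marker features on each of the 6 arrays. Points are arrays, solid bars are group means, dotted bars are each array's background floor for that feature, and the dashed line is the scanner ceiling. Knamycin lies at 15.28 to 15.38 in the 4 line arrays and at 8.36 and 8.89 in WT.

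The comparison of RCc3::OsERF71 with WT asked which root transcripts differ when OsERF71 is driven by the root promoter. Genes encoded in the organelles were lower in this line. Of 84 plastid features above background on both WT arrays 81 fell, and all 46 such mitochondrial features fell. Over all 108 plastid and 53 mitochondrial features, those below background included, the median log2 changes were -1.53 and -1.60. Both shifts passed limma's camera test with a preset correlation (adjusted p = 8.9e-13 for plastid and 4.7e-12 for mitochondrial features). Neither passed with an estimated correlation (adjusted p = 0.34 and 0.31). Many of these features dropped to background in the line. With line values held at the floor, the median was -1.23 over the 84 plastid features and -1.36 over the 46 mitochondrial features.

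Each functional group of organelle genes moved the same way in RCc3::OsERF71, counted over the features above background on both WT arrays. All 4 features of the plastid-encoded RNA polymerase fell, among them rpoB by at least 3.93-fold (limma, adjusted p = 4.7e-06) and rpoC1 by at least 5.84-fold (limma, adjusted p = 8.8e-07). Of 12 features of the plastid NDH complex, which takes part in cyclic electron flow, 11 fell, including ndhB by at least 2.86-fold. In photosystem I, 3 of 3 features fell, with psaA lower by at least 2.91-fold. In photosystem II, 6 of 6 fell, with psbF and psbZ lower by at least 1.65-fold and 1.53-fold. All 6 plastid ATP synthase features fell, atpE by 5.13-fold and atpA by at least 2.74-fold. All 22 plastid ribosomal protein features fell, rps4 by 4.52-fold and rps14 by at least 1.33-fold. The line mean of rps4, 10.23 on the log2 scale, lay below the single-probe floors of 10.42 and 10.32 on these arrays, so its fold is uncertain. In the cytochrome b6f complex 2 of 2 fell, petA by at least 2.57-fold, and cemA, for a plastid envelope membrane protein, fell by at least 2.01-fold. In mitochondria, all 8 features of respiratory complex I fell, nad9 by 4.99-fold and nad3 by at least 3.37-fold. All 7 features of complexes III and IV and the ATP synthase fell, cob by at least 2.11-fold and atp6 by at least 2.99-fold. All 9 mitochondrial ribosomal protein features fell, rps12 by at least 4.17-fold and rps4 by at least 2.32-fold. All 17 unnamed mitochondrial reading frames fell, orf183 by at least 2.88-fold and orf241 by at least 2.16-fold. The largest adjusted p among these named genes was 0.0012 (limma, nad9), and nad9 lost its call with an intensity trend and robust variance (adjusted p = 0.053). By camera with the preset correlation the adjusted p of the groups of 5 or more features ranged from 8.3e-07 (unnamed mitochondrial reading frames) to 0.0048 (complexes III and IV with ATP synthase). None passed with an estimated correlation, where the adjusted p lay between 0.31 and 0.36. The only named organelle gene that rose was the plastid reading frame OrsajCp105, by 1.30-fold (limma, adjusted p = 0.0037).

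Across all features, 21376 of 27614 (77.4%) differed between RCc3::OsERF71 and WT (limma, adjusted p under 0.05), 10377 higher and 10999 lower. Of these, 3406 changed at least 2-fold, 1441 upward and 1965 downward. The balance of directions depended on the scaling, with 11131 called higher and 8937 lower under median scaling. The groups did not overlap for 88.3% of features, against 33.3% by chance for 2 arrays against 2. The cDNA feature AK065283 was higher by at least 38.1-fold and AK100853 by at least 19.3-fold, both with WT not above background. AK101283 was lower by at least 17.5-fold and AK064432 by at least 13.9-fold. Against a stricter floor, from single random probes, these bounds were 12.5-fold, 6.32-fold, 4.62-fold and 3.68-fold, in the same order. The array dates differ between these groups and each date holds arrays of 1 group, so no value within a date could be had. The random-probe sets, which should carry no gene signal, also differed after normalization. Of 11454 sets 6271 were called brighter in RCc3::OsERF71 and 4 dimmer, with a median log2 change of 0.26. Before normalization the median random-probe intensity was not higher in this line (162 and 167, against 187 and 167 in WT).

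The comparison of GOS2::OsERF71 with WT put the same question for the promoter active throughout the plant. Organelle genes were lower here too, by smaller amounts. Of 84 plastid features above background on both WT arrays 71 fell, and of 46 such mitochondrial features 35 fell. The medians over all 108 and 53 features were -0.80 and -0.75. Camera with the preset correlation gave adjusted p = 1.5e-06 for plastid and 8.9e-06 for mitochondrial features, and with an estimated correlation adjusted p = 0.36 for each. With line values held at the floor the medians over the features above background in WT were -0.79 and -0.75.

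Counted over the same features in GOS2::OsERF71, all 12 features of the plastid NDH complex fell, ndhF by at least 2.04-fold (limma, adjusted p = 0.00013) and ndhG by at least 1.10-fold (limma, adjusted p = 0.0032). All 6 plastid ATP synthase features and all 4 of the plastid RNA polymerase fell, with atpA lower by 2.41-fold (limma, adjusted p = 0.00051). Of 22 plastid ribosomal protein features 20 fell, rps4 by 2.68-fold and rps14 by at least 1.41-fold. In photosystem I, 3 of 3 fell, and psaA was lower by at least 3.06-fold (limma, adjusted p = 0.0012). In photosystem II 3 of 6 fell, and psbN and psbB were below background in both groups. In the cytochrome b6f complex 1 of 2 fell. The plastid maturase gene matK, which acts in intron splicing, fell by at least 1.31-fold (limma, adjusted p = 0.00013). In mitochondria, 6 of 8 features of complex I fell, nad6 by at least 1.74-fold (limma, adjusted p = 5.1e-06). Of 9 mitochondrial ribosomal protein features 8 fell, rps12 by 2.64-fold (limma, adjusted p = 0.00043) and rpl5 by at least 1.82-fold (limma, adjusted p = 3e-06). Of 7 features of complexes III and IV and the ATP synthase 4 fell, cox3 by 2.24-fold and cob by 2.02-fold. Of 17 unnamed mitochondrial reading frames 13 fell, orf183 by 2.57-fold and orf241 by at least 2.28-fold. By camera with the preset correlation, photosystem II (adjusted p = 0.13) and complexes III and IV with ATP synthase (adjusted p = 0.096) did not pass. The other groups of 5 or more features ranged from 0.00049 (plastid ribosomal proteins) to 0.034 (plastid ATP synthase), and with an estimated correlation none passed (adjusted p between 0.31 and 0.45). The plastid reading frame OrsajCp074 rose 1.34-fold (limma, adjusted p = 0.031), a call lost in the fit to the authors' values (adjusted p = 0.11).

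**Figure D2:**
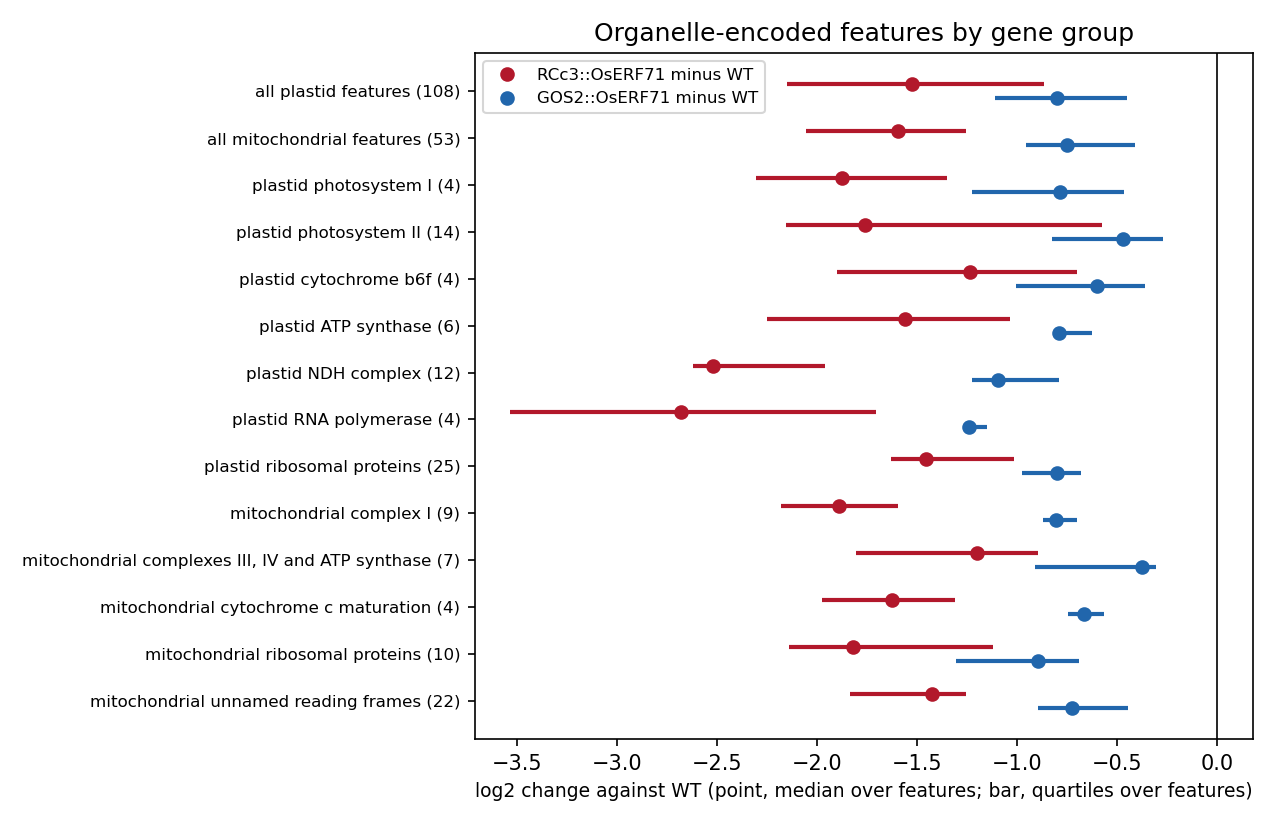
Log2 change against WT of organelle-encoded features by gene group, for both lines. Points are medians over the features of a group, bars run from the lower to the upper quartile, and the number of features stands in parentheses. The medians of all plastid features are -1.53 in RCc3::OsERF71 and -0.80 in GOS2::OsERF71.

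Over all features, 21585 (78.2%) differed between GOS2::OsERF71 and WT (limma, adjusted p under 0.05), 10088 higher and 11497 lower. At least 2-fold changes numbered 3360, of which 1794 were rises and 1566 falls. The groups did not overlap for 90.7% of features, against 33.3% by chance. AK065283 was higher by at least 35.2-fold and AK100853 by at least 19.9-fold (11.6-fold and 6.53-fold against the stricter floor), and AK101283 and AK064432 were lower by 1.85-fold and 2.60-fold. With the authors' values the call for AK101283 in this line was lost (log2 change -0.81, adjusted p = 0.084). All WT arrays shared 1 date and all GOS2::OsERF71 arrays another, so date and group cannot be told apart. Of the 11454 random-probe sets 5226 were called brighter in this line and 50 dimmer (median log2 change 0.23).

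The changes of the 2 lines against WT were set side by side to see how far they were shared. Both lines had 9236 features higher and 10038 lower than WT, and 147 were called in opposite directions. Independent lists of the same lengths would share 3791 higher and 4579 lower features. At a 2-fold minimum 1141 rises and 1166 falls were shared, against 93.6 and 111.4 for independent lists. The log2 changes correlated across features at r = 0.9065 (Spearman 0.9415). In 100 simulations, unchanged groups that shared simulated WT arrays gave r = 0.502, ranging from 0.487 to 0.521. The covariance of the log2 changes was 0.4514 against a simulated 0.00459. The simulated arrays varied only by the spread between replicates. Features are not independent replicates, and 2 WT arrays are too few to give each line 2 control arrays of its own, so part of the excess in overlap and correlation may come from the shared controls. Knamycin, sGFP, AK065283 and AK100853 were among the features called higher in both lines, and the medians of the organelle genes were lower in RCc3::OsERF71 than in GOS2::OsERF71.

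**Figure D3:**
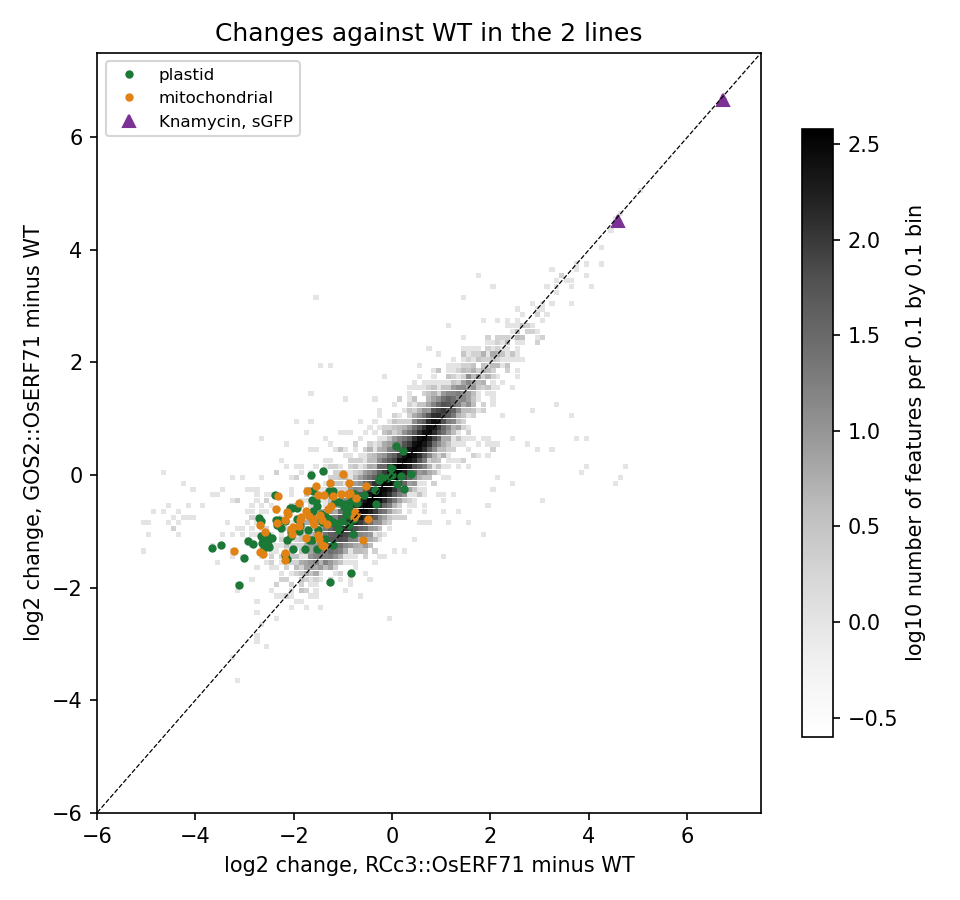
Log2 change against WT in RCc3::OsERF71 (horizontal) and GOS2::OsERF71 (vertical) for the 27614 features, in bins of 0.1 by 0.1 shaded by the log10 number of features. Green and orange points are plastid and mitochondrial features, purple triangles are Knamycin and sGFP, and the dashed line marks equal change. The correlation across features was r = 0.9065.

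The direct comparison of RCc3::OsERF71 with GOS2::OsERF71 asked where the 2 lines differed in root transcript levels. The arrays of the 2 lines fell on different dates, so line and date cannot be told apart here either. Organelle genes were again lower in RCc3::OsERF71. Of 108 plastid features 56 were lower, 15 of them below background in both lines, and 1 was higher (median log2 difference -0.67). Of 53 mitochondrial features 39 were lower, 11 of them below background in both lines, and 0 were higher (median -0.84). The lower features numbered 27 plastid and 21 mitochondrial without GOS2::OsERF71 replicate 1, 26 and 21 without replicate 2, and 30 and 25 with an intensity trend and robust variance. Camera with the preset correlation gave adjusted p = 6.1e-22 and 6e-23, and with an estimated correlation adjusted p = 0.31 for each. Over the 84 plastid and 46 mitochondrial features above background on both WT arrays, with values held at the floor, the medians were -0.38 and -0.66. The plastid RNA polymerase genes rpoB and rpoC1 were lower by at least 1.60-fold (limma, adjusted p = 0.00058) and 2.47-fold (limma, adjusted p = 6.1e-05). The photosystem II gene psbZ was lower by at least 1.19-fold (limma, adjusted p = 0.0033) and petA by at least 1.52-fold (limma, adjusted p = 0.0049), calls lost with an intensity trend and robust variance (adjusted p = 0.052 and 0.071). The complex I gene nad9 was lower by 3.87-fold (limma, adjusted p = 0.027). This call was lost in the same setting (limma, adjusted p = 0.21), with the authors' values (0.067) and in the fit to 2 groups (0.064). OrsajCp105 was 1.28-fold higher (limma, adjusted p = 0.036). This call was lost under median scaling (limma, adjusted p = 0.31), with the authors' values (0.072), with the replicate block (0.061) and with a normexp offset of 0 (0.051). AK101283 and AK064432 were lower by at least 9.43-fold and 5.36-fold, and by at least 2.49-fold and 1.42-fold against the stricter floor. The plastid median log2 per array, relative to the WT mean, was -1.73 and -1.21 in the RCc3::OsERF71 arrays and -0.80 and -0.76 in the GOS2::OsERF71 arrays. Without RCc3::OsERF71 replicate 1 the median plastid difference between the lines was -0.39.

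In all, 3049 features (11.04%) differed between the lines (limma, adjusted p under 0.05), 1307 higher and 1742 lower in RCc3::OsERF71. At least 2-fold differences numbered 334, of which 74 were higher and 260 lower. Of the 3049 features, 1786 were also called in both lines against WT in the same direction, 147 in opposite directions, 543 in RCc3::OsERF71 alone and 538 in GOS2::OsERF71 alone. None of the 11454 random-probe sets was called (limma, 0 higher and 0 lower). The count depended on single arrays and on the scaling: it was 1717 without RCc3::OsERF71 replicate 1, 941 and 903 without GOS2::OsERF71 replicate 1 or 2, 9142 under median scaling (6218 higher, 2924 lower), 1996 with the authors' values and 8828 with the date as a random block.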

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

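Of the tests in this part, those on cyclic loess alone, on the marker probes, on green tissue, on RNA purification and on single-probe features were chosen after the results had been seen.

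The lines differed from each other at 3049 features by limma's direct test. The median log2 difference, RCc3::OsERF71 minus GOS2::OsERF71, was -0.668 over plastid and -0.836 over mitochondrial features. Among named genes it was -2.377 for rpoB, -2.249 for rpoC1, -2.03 for psbZ, -1.957 for petA, -1.953 for nad9 and 0.359 for OrsajCp105, and among unnamed features -4.208 for AK101283 and -3.632 for AK064432. Except for nad9 and OrsajCp105, RCc3::OsERF71 was not above background for these genes, so their differences are only bounded, at 1.60-fold, 2.47-fold, 1.19-fold, 1.52-fold, 9.43-fold and 5.36-fold or more in the order given (2.49-fold and 1.42-fold for the last 2 with a floor from single random probes). After normalization the random probes, outside the gene measurement, were brighter in both lines than in WT. Of the random sets 6271 were called brighter in RCc3::OsERF71 and 5226 in GOS2::OsERF71. The median intensity of random probes before normalization was 187 and 167 in WT, 162 and 167 in RCc3::OsERF71, and 224 and 256 in GOS2::OsERF71. The medians of RCc3::OsERF71 did not exceed those of WT, so its rise is relative to the gene probes.

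Both lines differed from WT at 19274 features in the same direction. Chance variation of the size seen between replicates does not account for this. The covariance of the changes was 0.4514, and the highest of 100 simulations gave 0.00485. A deviation that both WT arrays share, such as one of their date, was not part of the simulations, which therefore cannot exclude it. Labelling, hybridisation or scanning of the WT arrays apart from the others remains a candidate explanation for many small shared changes: random sets were called in both lines at 0.734 times the rate of gene features of the same brightness (41.9% against 57.0%), and the WT arrays carry a date of their own. A background shift does not account for dim features that changed at least 2-fold in both lines, where the ratio was 0 (0% of random sets against 3.66% of gene features), although brighter features lie outside this test. Cyclic loess, which removes a brightness-dependent trend, kept 97.1% of the shared calls and 76% of the calls between lines, which argues against such a trend as the whole cause. A part of it stays open because median scaling kept 79.6%, just under the 80% set beforehand for both settings, and so does an effect of OsERF71 overexpression, which date and group keep from being told apart.

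The Knamycin and sGFP features were bright in both lines. Cross-hybridisation at single probes is argued against by all probes of both features: 100% of their 8 probes were at least 4-fold brighter on every line array than on both WT arrays, and against the higher of WT and the background floor they were brighter by at least 15.3-fold to 47.5-fold. A candidate explanation is that the lines carry these marker genes in their transgene, which the labels do not describe and which was not tested.

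Organelle genes were lower in both lines, further in RCc3::OsERF71. Mitochondrial genes fell by 0.824 times the median fall of the photosystem genes in RCc3::OsERF71 and by 1.34 times in GOS2::OsERF71. This argues against more green tissue in the WT roots as the whole cause. In RCc3::OsERF71, 1 of 3 photosystem I, 4 of 6 photosystem II and 18 of 46 mitochondrial features lay at the floor. In GOS2::OsERF71 these numbers were 1, 1 and 8. Falls are cut short at the floor, so the ratio in RCc3::OsERF71 is uncertain and a part of this cause stays open. Features with a single probe as such do not account for the whole fall. Random single probes of the same WT brightness rose by a median log2 of 0.836 in RCc3::OsERF71 and 0.848 in GOS2::OsERF71. The ratios to the organelle change were at most -0.513. This rise exceeded the medians of 0.26 and 0.23 over all random sets of 10 probes. Single probes of cDNA features changed by medians of -0.12 and -0.19 against -1.63 and -0.81 for single-probe organelle features. Less carry-over of organelle RNA in the poly(A) purification of the lines stays open. Of the features above background on both WT arrays, 97.6% and 81.7% fell in the 2 lines. They were counted here over the 80 plastid features with a gene name and the 46 mitochondrial ones. The falls correlated across features at a Spearman value of 0.642 in plastid and 0.404 in mitochondrial genes. Both falls share the WT arrays, and simulated unchanged lines gave 0.479 over all features, so these correlations cannot decide the question. A biological difference between the lines and WT was not tested apart from these.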

How the results depend on the processing

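The counts against WT and the shared count stayed within 1.5 times under every alternative without a fold minimum, and all 6 organelle medians stayed negative. Median scaling turned the balance of RCc3::OsERF71 against WT to 11131 higher and 8937 lower, and of shared features to 8260 higher and 7860 lower. At least 2-fold, the counts were 3406 (RCc3::OsERF71 against WT), 3360 (GOS2::OsERF71 against WT), 334 (between lines) and 2307 (shared, chosen after seeing the data). The count between lines was 9142 under median scaling, where 68% were higher against 42.9% in the reported fit and the median of all features moved to 0.1029, 1996 with the authors' RMA values, 8828 with the date as a random block and 4891 at an adjusted p under 0.1. The estimated date correlation of -0.73 arises because the 2 arrays of a group always deviate oppositely from their own mean, so that fit says little. The cause of the other moves was not tested. Leaving out 1 array, where a lone array is assumed to vary like the other groups, gave 903 (without GOS2::OsERF71 replicate 2) to 3464 features between lines, 941 without GOS2::OsERF71 replicate 1 and 1717 without RCc3::OsERF71 replicate 1. It gave 19407 to 20669 for RCc3::OsERF71 and 19222 to 21963 for GOS2::OsERF71 against WT, 17213 to 18920 shared features, and the plastid difference between lines ran from -0.975 to -0.394. With the replicate number as a block the counts were 21120, 21460 and 2469, with 19089 shared. The numbers do not pair the samples: differences between replicates 1 and 2 correlated at -0.212 (WT with RCc3::OsERF71), 0.126 (WT with GOS2::OsERF71) and 0.123 (between lines). Of 1150 values of named features under 18 other settings, 1122 kept direction and call, 28 lost the call and 0 reversed. These features were chosen for large, called changes without overlap in the reported fit. Some settings also leave the estimates unchanged, so the lack of reversals says little. The OsERF71 change and the pathway lists were not run under any setting, and gene sets were not run with the date block. Signal over background limits the falls, since 29 of 84 plastid features lay at the floor in RCc3::OsERF71.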

Other observations

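Changes of neighbouring features on the chromosomes correlated weakly, at r = 0.12 and 0.118 against WT and 0.0893 between the lines (highest of the shuffles 0.0118, 0.0206 and 0.0167), and single windows stood out. These windows were chosen after their values were seen. The highest mean among windows of 15 neighbouring features lay on chromosome 11 in both contrasts to WT, from position 28091299 to 28135221 in the array design's coordinates. All 15 features were called higher in each line, with a mean log2 change of 1.90 in RCc3::OsERF71 (range 0.84 to 3.93) and 1.90 in GOS2::OsERF71 (0.91 to 3.58). In 1000 shuffles of feature order 0 gave a mean as high, and the 95th percentile of the highest mean was 0.917 and 0.914. The lowest window in RCc3::OsERF71 lay on chromosome 2 from 2905890 to 2983038, where 14 of 15 features were called lower in each line, the remaining feature was called higher in GOS2::OsERF71, and the means were -1.42 and -0.94. Neighbouring genes of similar sequence can share probes' signal, which was not tested.

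Between the lines, the lowest window lay on chromosome 12 from 5857344 to 6575793, with a mean log2 difference of -1.10 and 11 of 15 features lower in RCc3::OsERF71 (0 of 1000 shuffles as low). The highest lay on chromosome 4 from 6440297 to 6901111, with a mean of 0.77, 5 of 15 features higher and 1 lower (1 of 1000 shuffles as high). Its changes against WT ranged from -1.40 to 4.63 in RCc3::OsERF71 and from -1.43 to 0.71 in GOS2::OsERF71. The feature at 4.63 thus differed strongly between the lines and weighs on this mean.

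On chromosome 6, 9 cDNA features lie between the loci Os06g0193200 and Os06g0196200, whose numbers flank the one sought for OsERF71. Of these, 1 was called higher in both lines and 0 at 2-fold or more, with highest log2 changes of 0.57 and 0.49. None was assigned to OsERF71. AK065283, the cDNA feature with the largest rise in RCc3::OsERF71 and far higher in GOS2::OsERF71 too, was also placed on chromosome 6. It lies outside this interval and was not assigned to a gene.

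Locus features and cDNA features shifted apart: the median log2 change was 0.22 and 0.20 over 6941 locus features and -0.08 and -0.12 over 20507 cDNA features, in RCc3::OsERF71 and GOS2::OsERF71. The random-probe sets, which match no gene, shifted by medians of 0.26 and 0.23. The medians of the locus features did not exceed these, so no shift of these genes beyond background is claimed.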
